A study of Mus musculus with 4 samples.

How the data were processed

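TOP2B cleavage complexes were measured in cultured mouse cortical neurons treated with etoposide. Per the labels' protocols, complexes were isolated by native TOP2B ChIP from sonicated lysates, one strand was digested with lambda exonuclease after adapter ligation, and libraries were made by linear amplification. The labels give 2 ChIP libraries and 2 input libraries. Nothing in the labels says whether these came from separate cultures.

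The deposited data used here were 1 peak list in narrowPeak layout, pooled by the authors over libraries, without a header. FastQC, Trimmomatic, BWA, SAMtools and MACS2 are named in the submitters' processing notes, without versions, with builds mm10 and GRCm38.p6. The caller's settings, the treatment of duplicates, the filters and which libraries were pooled are not given in the sources used here. In the list deposited by the authors, column order and MACS2 conventions identify the fold enrichment, a linear ratio of pileup over control at the summit. The −log10 p and −log10 q of each peak are the authors' deposited values as well. The display score is a deposited whole number and was not tested. Interval and summit positions in the deposited list are in bp and were turned into 1-based coordinates. The smallest −log10 p in the list was 2.00. Depth per library is unknown, so no value has an interval for depth, and pooled peaks allow no comparison of replicates or of ChIP with input.

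Pileup and control level at each summit were reconstructed from the deposited fold and p. MACS2 writes fold as pileup over control with 1 added to each, and p from a Poisson tail, and a whole-number pileup satisfying both within 0.002 of −log10 p was sought. It was unique for 35536 of 35539 peaks (99.99%). The other 3, with very large pileups or p-values, were solved separately, and that of the highest −log10 q is approximate.

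Genes were taken from a RefSeq gene table of GRCm38.p6, with 49554 genes on the 20 chromosomes of the list, 21631 of them protein-coding. The table gives gene start, end and type, but neither strand nor exons, and no genome sequence was used here. Promoters, as planned, were therefore replaced by windows of 1 kb around either end of a protein-coding gene. Exon, intron and UTR classes, base composition, CpG content and motifs at summits were not analysed here, nor were a background outside repeats and lists stratified by CpG. Random positions were drawn between the first and last summit of each chromosome, and runs of unknown bases could not be avoided. The 34 entries on scaffolds and patches of the build were left out of all comparisons.

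Each summit was placed in 1 of 4 classes, in order: near a gene end, elsewhere in a protein-coding gene, in another gene, or outside listed genes. Shares were compared with 1000 sets of random positions, as many per chromosome as observed, and two-sided permutation p-values were taken from the distance to the random mean. Ranges of a ratio are the observed value over the 95% range of the random sets. Folds at gene ends and elsewhere were compared by the difference of median log2 fold with 100000 permutations. Gene lists were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 19 lists, 14 fixed by symbol and 5 by symbol pattern. Gene bodies were trimmed by 1 kb at both ends, genes over 3000 bp were split into 5 groups by length, and density per group was compared with the random sets. Neighbouring summits were compared by median distance and by the share within 5 kb. Peak density was correlated with gene density across autosomes with 100000 permutations.

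Named genes followed a fixed rule. They were the 10 protein-coding genes with the highest-fold end summit (9, since 11 genes tied for the last place and are given as a count), the 10 with most summits in gene and windows, and up to 3 members of each list with the highest-fold end summit. Top2b, Top2a, Fos, Npas4, Egr1 and Bdnf were always named, with the 5 peaks of highest fold and the 5 widest. Genes beside peaks that rank high by q, and Klf4, were named after their values were seen. Some genes that the rule selects are not reported here.

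The lists, tests, named-gene rule and a first group of other settings were set before the data were examined. That group held stricter lists (fold at or above the median, −log10 q of at least 5), merged entries, autosomes only, windows of 500 bp and 5 kb, overlap of the whole interval, ends of all genes, only genes with a summit, bodies from 5 kb inside, folds within width groups, and neighbours within 20 kb. Chosen after seeing the data were q of 0.05 or less, peaks of high control level left out, random positions within 50 kb, lists stratified by gene count within 500 kb, means of log2 fold, immediate early genes without Fos, genes of each list with an end summit against random positions, and the comparison of 10 gene types.

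The tests were tried on simulated summits. A pileup was recovered for 100% of 3000 simulated peaks. With no planted excess, 4.75% of 400 sets of 35505 random summits passed the gene-end test at 0.05. This larger run was added because a first trial, with fewer runs and fewer random sets, had exceeded that rate. Planted gene-end folds of 1.1, 1.25 and 1.5 were recovered as 1.10, 1.25 and 1.50, and 90%, 100% and 100% of 40 runs passed. For a list of 20 genes, 31% of 100 runs passed when 20% of members were given an end summit and 100% when 40% were, so a list of that size can miss a moderate excess. For 60 genes, 100% passed at 20%. In these list runs the summits were random, so 4.8% of 20 genes had one with none given, against 8.30% of genes in the data. They also multiplied p by the number of lists in place of the Benjamini-Hochberg adjustment, so the rates hold for that setting only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.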

Results

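TOP2B cleavage complexes were mapped in cultured cortical neurons from embryonic Swiss-Webster mice. TOP2B is the type II topoisomerase of neurons, which cuts both DNA strands and stays covalently bound to the ends while they are open. Etoposide, a drug that blocks religation, was given at 50 µM for 30 min before collection so that these complexes persisted. The labels describe 4 libraries, 2 of TOP2B chromatin immunoprecipitation (ChIP) and 2 of input DNA. The values analysed here were a single peak list pooled over libraries, so no value carries a standard deviation or an n, and the depth of each library is unknown. All tests below describe this list and not the variation between cultures. Coordinates are those of mouse build GRCm38 and are 1-based.

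The list held 35539 peaks, of which 35505 lay on the 19 autosomes and X. They were narrow, with a median width of 222 bp, and 7943 of them (22.4%) had the minimum width of 190 bp. The median fold enrichment over control, as the authors' caller gave it, was 2.77 (quartiles 2.49 and 2.94). A whole-number pileup could be reconstructed from fold and p for nearly every peak. The median summit held 15 ChIP fragments (quartiles 14 and 17) against the most common control level of 4.78. That level was also the lowest in the list and was shared by 25262 peaks (71.1%). Folds at these peaks therefore compare with a common level, not with one particular to the site. The q-value at the median peak was 0.110, and 8334 peaks (23.5%) had a q of 0.05 or less.

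The immediate early gene Fos, a transcription factor gene induced by neuronal activity, carried the peak of highest fold in the list. Its fold was 49.6, with 286 fragments at the summit against a control level of 4.78, the common lowest level, and a −log10 q of 381.7. The next fold on the chromosomes was 4.84, so the Fos peak stood 10.25 times above it. The peak spanned chromosome 12 from 85473292 to 85474955 and was also the widest, at 1664 bp. It began 598 bp outside the lower-coordinate end of Fos and reached 1065 bp into the gene, with its summit 121 bp inside that end.

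Other genes with a strong summit at an end had folds near 4 to 5. Etnk2, which encodes an ethanolamine kinase, had a fold of 4.76 on chromosome 1, with the summit at 133363838, 375 bp inside its lower end. Tmem51 had a fold of 4.50 at 142084519 on chromosome 4. A fold of 4.15 was found at Vash1, at Jam2, a junctional adhesion gene, at Diras1, a Ras-family GTPase gene, and at a single summit shared by Ccnd3, which encodes a D-type cyclin, and its neighbour Bysl. Ptpn4, a tyrosine phosphatase gene, followed with 4.05, and 11 further genes tied at 3.98. Peaks away from gene ends reached similar values. Shank3, a postsynaptic scaffold gene, held a peak at 89548992 to 89549714 on chromosome 15 with a fold of 4.84. Prkar1b, which encodes a regulatory subunit of protein kinase A, held another of 4.84 at 139127438 to 139127767 on chromosome 5. The same fold was found outside listed genes at 95841563 to 95841832 on chromosome 12.

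Ranking by q put different regions beside Fos. The entry with the highest −log10 q (911.2) lay on chromosome 2 from 98666982 to 98667279, with a fold of only 1.44 over a control level of about 25350. Entries at and beside Rn18s-rs5, a ribosomal RNA pseudogene on chromosome 17, included intervals of 1191 bp and 1073 bp, among the 5 widest of the list, with folds of 1.44 and 1.57. A peak inside Chl1, a neural cell adhesion gene, had a fold of 1.26 over a control level of 3826. The other entries among the widest were 904 bp on a scaffold, with a fold of 2.07, and 888 bp at 125308274 on chromosome 10, with a fold of 2.77. Across the list, 123 entries had a control level more than 2 times the most common one.

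**Figure D1:**
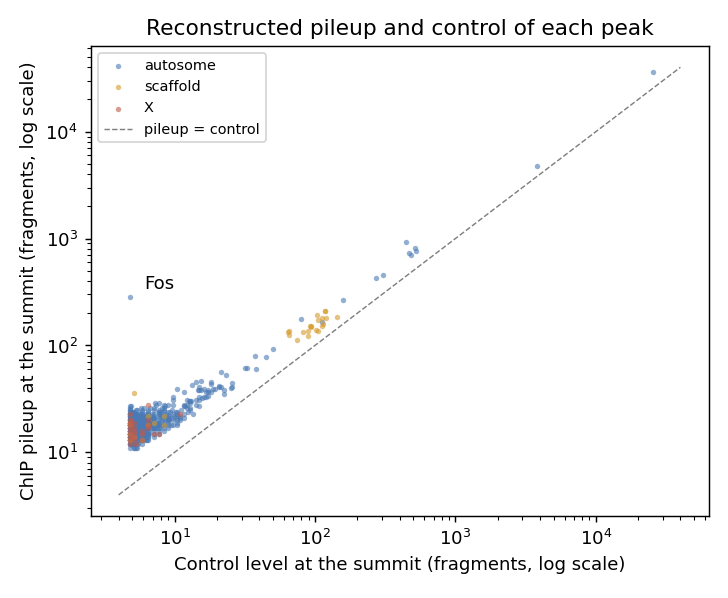
ChIP pileup (vertical, fragments, log scale) against control level (horizontal, fragment units but not whole numbers, log scale) at each summit. Both were reconstructed from fold and p, for autosomes, X, and scaffolds and patches (labelled scaffold), and the dashed line marks equal values. Fos lies alone at a pileup of 286 over a control level of 4.78, while the entries of very high pileup have control levels to match.

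Whether cleavage complexes gathered near genes was tested against random positions on the same chromosomes. Summits within 1 kb of an end of a protein-coding gene numbered 1737 of 35505, or 4.89% (95% Wilson interval 4.67 to 5.12). Random positions gave 3.15%, so gene ends held 1.56 times the random share (range from the random sets 1.47 to 1.65). The rest of protein-coding genes held 46.3% of summits against 39.4% at random (1.17 times). Other listed genes held 7.50% against 8.24% (0.911 times), and sequence outside listed genes 41.3% against 49.2% (0.840 times). Each of these 4 shares had a two-sided permutation p of 0.001, the smallest that 1000 random sets can give, and an adjusted permutation p of 0.001. The excess was highest 250 to 500 bp from an end, at 1.70 times, and fell to 1.28 times at 2000 to 5000 bp. Among protein-coding genes, 1796 of 21631 (8.30%) had a summit at an end, against 5.41% at random. When random positions were kept within 50 kb of each summit, the gene-end share was 1.20 times random (1.14 to 1.26). The other shares then lay nearer to random but still past the threshold. They were 1.03 times in the rest of protein-coding genes (permutation p 0.001), 0.967 times in other genes (permutation p 0.013) and 0.958 times outside listed genes (permutation p 0.001), all two-sided. The excess at 2000 to 5000 bp was 1.03 times on that background. The annotation used here did not tell a gene's start from its end.

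Fold enrichment at gene ends was close to that elsewhere. The median fold was 2.77 both at the 1737 gene-end summits and at the other 33768, with a two-sided permutation p of 1. Folds are heavily tied because pileups are small whole numbers. The means of log2 fold were 1.47 and 1.45, and their difference of 0.02, compared after the data were seen, had a two-sided permutation p of 0.0018.

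**Figure D2:**
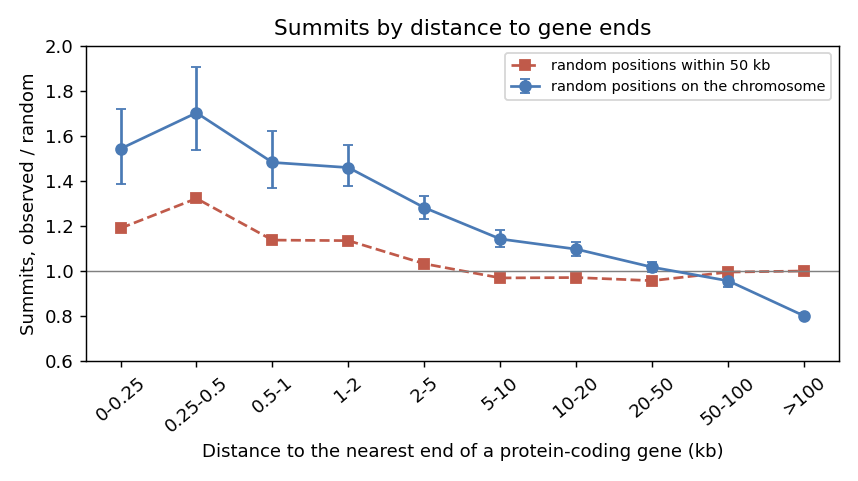
Summits observed over random (vertical) by distance to the nearest end of a protein-coding gene (horizontal, kb), against random positions on the chromosome (circles, bars show the 95% range of the random sets) and within 50 kb (squares). The ratio is highest at 250 to 500 bp, 1.70 by chromosome and 1.32 within 50 kb.

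Olfactory receptor genes, the odorant receptor family of the nasal epithelium, had summits at their ends less often than other protein-coding genes. Such a summit was found at 40 of 1110 members (3.60%) against 8.56% of the remaining genes. The odds ratio was 0.40 (95% interval 0.28 to 0.55), with an adjusted p of 3.68e-09 by Fisher's exact test, two-sided, over 19 lists. That test takes genes as independent, which genes lying beside each other are not. Olfr699, Olfr887 and Olfr1349 had the highest folds of the family, 3.29, 3.23 and 3.11. Compared with other genes within groups of like gene count over 500 kb, the odds ratio was 0.31. The 40 members with an end summit were 0.772 times the number given by random positions on the chromosome (unadjusted permutation p 0.0979, adjusted permutation p 0.372, two-sided). They were 1.21 times the number given by positions within 50 kb (unadjusted permutation p 0.242, adjusted permutation p 1), so the family differed from other genes but not past the threshold from random positions.

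Immediate early genes had end summits at 4 of 22 members (18.2%), with an odds ratio of 2.46 (0.60 to 7.47) and an adjusted p of 0.788 by Fisher's exact test. Beside Fos these were Egr3 (fold 3.29), Egr2 (3.11) and Klf4 (3.11), the last named outside the fixed rule because it completes the count. The 4 members were 3.12 times the number given by random positions on the chromosome (unadjusted permutation p 0.034, adjusted permutation p 0.372, two-sided). They were 1.71 times the number given by positions within 50 kb (unadjusted permutation p 0.264). Egr1 had no summit in the gene or its windows. Npas4, a neuronal activity-induced transcription factor gene, had 1 summit, which lay away from its ends, and Bdnf, the neurotrophin gene, likewise had 1. With only peaks of q 0.05 or less, a choice made after the data were seen, the same count of 4 members gave an odds ratio of 10.4 (2.56 to 31.8) and an adjusted p of 0.00994 by Fisher's exact test. Without Fos that ratio was 7.80 (1.47 to 26.9), with an adjusted p of 0.0881 by the same exact test.

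No other list passed the test. Of neuronal lists, late activity-regulated genes had end summits at 1 of 18 members (Kcna1, fold 3.11) and cortical excitatory genes at 1 of 20 (Bcl11a, 2.59). Inhibitory neuron genes had 1 of 18 (Sst, 2.77) and pan-neuronal genes 3 of 20 (among them Map2, 2.77, and Rbfox1, 2.59). Glutamate receptor genes had 2 of 23 (Grin2d, 2.77, and Grik3, 2.25). Among markers of other cell types, neural progenitor genes had 2 of 16 (Fabp7, 2.76, and Notch1, 2.22), and astrocyte genes 2 of 15 (Gfap, 3.46, and Gjb6, 2.25). Oligodendrocyte lineage genes had 2 of 15 (Cnp and Cspg4, both 3.11), and microglial and endothelial genes 3 of 17 (Kdr, 3.63, Csf1r, 2.59, and C1qb, 2.49). Liver and muscle genes, not expected in this tissue, had 2 of 20 (Myh1, 2.42, and Ckm, 2.10). Housekeeping genes had 1 of 20 (Eef1a1, 3.11). Ribosomal protein genes had 8 of 81, led by Rpsa (3.46), Rpl31 (3.24) and Rpl26 (3.11). Histone genes had 3 of 62 (H1f5, 3.63, and H2ac1 and H2bc1, which share a summit of 3.11). Hox genes had 3 of 39 (Hoxc6, 2.77, Hoxd8, 2.71, and Hoxc12, 2.59), and clustered protocadherins 3 of 57 (Pcdhgb6, 2.93, Pcdhgb2, 2.77, and Pcdhgb1, 2.59). Topoisomerase, cohesin and break repair genes had 2 of 21 (Smc3, 2.77, and Prkdc, 2.35). Top2b, which encodes the enzyme that was precipitated, held 3 summits and its paralogue Top2a 2, none of them at the ends. Adjusted p-values of these lists ran from 0.788 to 1 by Fisher's exact test, and lists of this size leave wide intervals. The deposited q of the end summits named here ran from 0.00437 (Kdr and H1f5) to 0.405 (Grik3 and Gjb6). It was 0.106 or more at folds of 2.77 and below, and 0.039 or less at the others. Low folds are thus weak evidence for a single gene. The q limit used above for immediate early genes left 1 to 3 genes in some of these lists. It left none in the cortical excitatory, inhibitory, pan-neuronal, glutamate receptor, neural progenitor, liver and muscle, Hox and break repair lists.

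**Figure D3:**
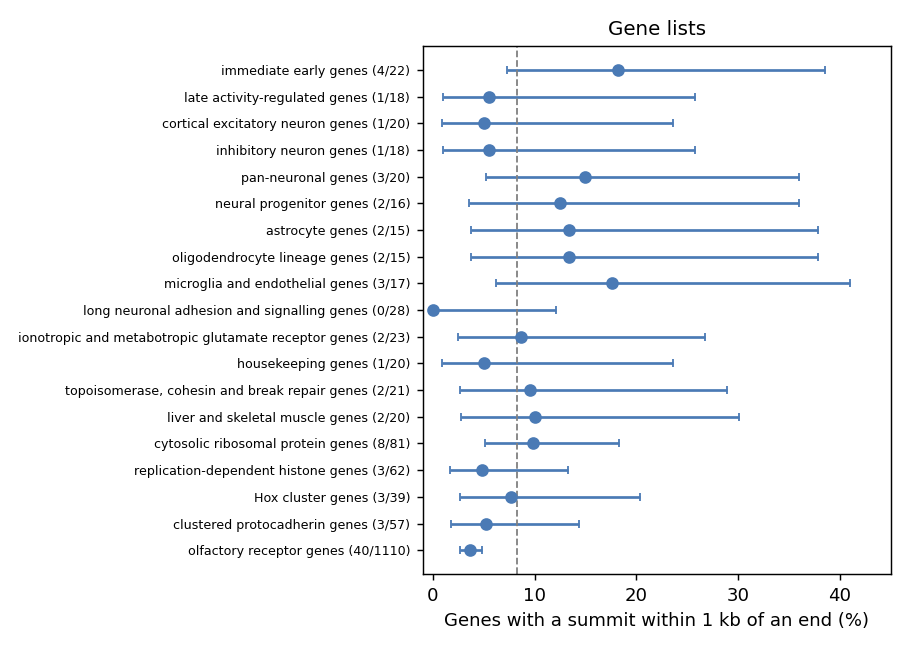
Percent of each list's genes with a summit within 1 kb of an end (points, with 95% Wilson intervals); numbers beside the names give genes with a summit and genes in the list, and the dashed line marks the 8.30% of all protein-coding genes. The olfactory receptor genes, at 3.60%, are the one list whose interval does not reach the line.

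Long genes held the most summits in number and short genes the most per length. Ptprd, a receptor tyrosine phosphatase gene, held 39 summits in 2270.5 kb, Lsamp, a neuronal adhesion gene, 33, and Dlg2, a synaptic scaffold gene, 29. Sdk1 held 28, Pcdh15 and Ccser1 25 each, and Nav2 and Cntnap2 23 each. These genes had 1.03 (Cntnap2) to 3.52 (Nav2) summits per 100 kb. Over the 18415 genes long enough to test, the shortest quintile, with a median length of 5.31 kb, had 2.89 summits per 100 kb of gene body, 2.01 times random (1.75 to 2.31). The longest quintile, with a median of 124.5 kb, had 1.51 per 100 kb, 1.07 times random (1.05 to 1.09). The quintiles between had 1.80, 1.42 and 1.34 times the random density, and all 5 had a two-sided permutation p of 0.001, the smallest possible here. The body of a gene of 5.31 kb lies wholly within 5 kb of an end, where summits were already in excess. With bodies taken from 5 kb inside the ends, the shortest quintile of the genes long enough for that had 1.73 times random (two-sided permutation p 0.001). Among genes with at least 1 summit, the shortest quintile had only 1.05 times random, with a two-sided permutation p of 0.0609. Against random positions within 50 kb, the shortest quintile had 1.33 times (1.19 to 1.50), and the longest had 1.01 times with a two-sided permutation p of 0.104.

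The 28 long neuronal adhesion and signalling genes, a list that includes Ptprd, Lsamp, Dlg2 and Cntnap2, held 496 summits, 1.25 per 100 kb against 1.36 at random. The ratio was 0.917, with an unadjusted two-sided permutation p of 0.05 and an adjusted permutation p of 0.399. Against positions within 50 kb the ratio was 1.00, with an unadjusted two-sided permutation p of 0.561. None of the 28 had a summit at an end.

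**Figure D4:**
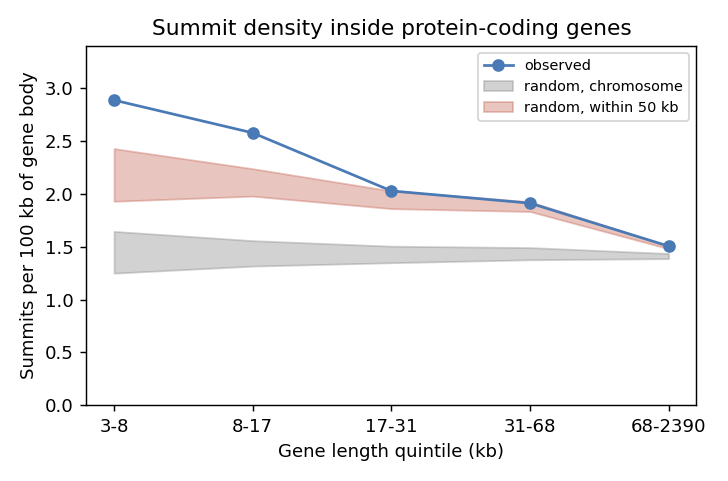
Summits per 100 kb of gene body (vertical) by quintile of gene length (horizontal, kb), observed (line) and as the 95% range of random positions on the chromosome (grey) or within 50 kb (red). Observed density falls from 2.89 in the shortest quintile to 1.51 in the longest.

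Chromosome X held few peaks. It had 190, or 1.16 per Mb between its first and last summit, against 14.8 per Mb on the autosomes, a ratio of 0.0783 (95% Poisson interval 0.0676 to 0.0903). Autosomes ranged from 11.9 per Mb on chromosome 14 to 18.4 on chromosome 11. Across the 19 autosomes, peaks per Mb rose with protein-coding genes per Mb (Pearson r 0.722, permutation p 0.00036; Spearman rho 0.723, permutation p 0.00065, both two-sided). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.689 with a permutation p of 0.00207. Intervals here cover counting error only.

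Summits lay closer together than random positions. The median distance between neighbours was 41360 bp against 47030 bp at random, and 17.3% of summits had another within 5 kb against 13.7% (1.26 times, 1.22 to 1.31). Both had a two-sided permutation p of 0.001, the smallest that 1000 random sets can give. The random positions spanned whole chromosomes, including runs of unknown bases, and none were kept within 50 kb here. Regional differences in peak density, or sequence where no peak can be called, can each bring this about, so local clustering was not shown.

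**Figure D5:**
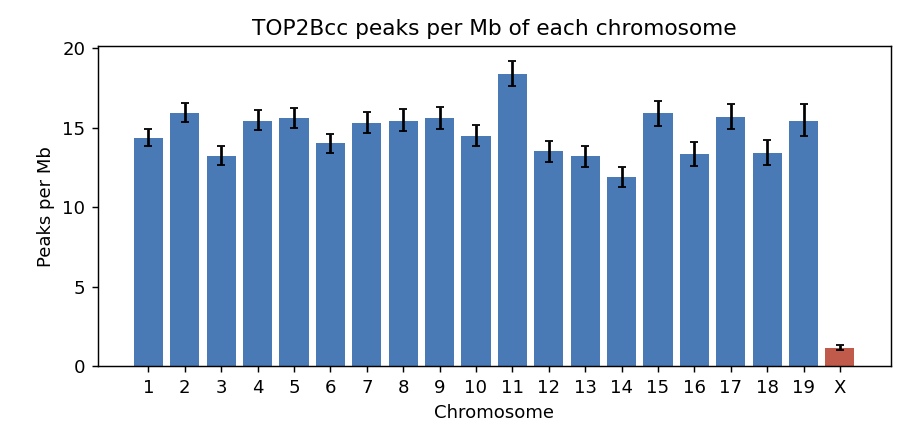
Peaks per Mb of each chromosome (bars, from 0), with 95% Poisson intervals as error bars. Chromosome X, at 1.16 per Mb, lies far below every autosome, the lowest of which, chromosome 14, has 11.9.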

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

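Of the tests in this part, those of the Fos peak, of the lowest folds and of the X control level, and the use of random positions within 50 kb, were chosen after the result was seen. No biological explanation was tested for any pattern, since the list holds a single condition.

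Entries on scaffolds and patches, which no comparison used, numbered 34. Of these, 21 lay on the unplaced scaffold JH584304.1, with a median control level of 102. The second-highest fold anywhere, 5.997, lay on KQ030494.1 from 506352 to 506810.

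The first pattern is the scarcity of peaks on chromosome X, at 0.0783 times the autosomal density. A lower number of genes on X is argued against as the whole cause, since more than 50 kb from any listed gene the ratio was still 0.1079 (0.0770 to 0.147). Chromosomes 12 and 18, with 5.83 and 5.87 protein-coding genes per Mb against 5.88 on X, had 13.5 and 13.4 peaks per Mb. That argues against gene density as more than a small part. Fewer X copies per cell in cultures that include male embryos may contribute, and 85.79% of X peaks had the lowest control level against 71.1% of autosomal peaks (Fisher's exact test, two-sided p 2.57e-06), consistent with lower X coverage in the control. Among peaks at the most common control level, which include 163 of the 190 on X, the odds that a peak lay on X changed by 0.9245 times per extra fragment (0.853 to 1.002), an interval that includes 1, so an effect of the caller's pileup threshold cannot be told apart from others. The sex of the embryos is not given in the labels used here.

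The second pattern is the Fos peak. Copies of a single amplified fragment are argued against as the whole peak, as its 1664 bp were 8.758 times the minimum width of the list and no entry was wider. High folds shared by the immediate early genes may be part of it, yet the highest fold at another member, Egr3, was 3.286, above 87.3% of gene-end summits and below their 95th percentile of 3.46, so 3 other members leave this open. Fragments of Fos present only in the ChIP libraries, from the cells or from handling, and copies of many fragments, could not be tested without values per library.

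The third pattern is the excess at gene ends. Differences between regions of 100 kb do not account for all of it, since random positions within 50 kb left 1.199 times (1.143 to 1.259), though less than the 1.56 seen against whole chromosomes. Peaks of the lowest folds lay at gene ends less often than the strongest, the ratio of shares being 1.257 (1.085 to 1.456). The 5 fold groups did not rise in order, and the lowest still held 1.38 times random. Peaks of equal fold fell on both sides of each boundary between groups, and their order in the list decided the side. The order of the middle groups therefore says little about fold, and the 1.257 rests partly on that split. Base composition, mappability and open chromatin stay open, as no sequence was used here.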

How the results depend on the processing

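Chosen after the result was seen were the settings q of 0.05 or less, high control levels left out, random positions within 50 kb, lists stratified by gene count, means of log2 fold, lists against random positions and lists without Fos. No paired analysis was possible because the only list is pooled and carries no replicate numbers, and for the same reason no library could be left out. Of the comparisons' main values under other settings, 79 kept direction and side of the threshold or stayed within their limits, 11 moved, 7 weakened, 2 reversed and 1 strengthened. Merging overlapping entries left all 35539 peaks as they were. Its values therefore stayed by construction, here and among single lists. Among single lists, 170 counted as staying, and 1 each weakened, strengthened and reversed. A list past the threshold in neither setting counted as staying even where its odds ratio changed direction. Late activity-regulated genes, for example, went from 0.65 to 2.74 at q of 0.05 or less. The peak count was 18707 at folds from the median, 8334 at q of 0.05 or less and 43 at −log10 q of at least 5. Genes with an end summit came to 4.669%, 2.103% and 0.01849% in these lists, and to 4.544% and 29.41% with windows of 500 bp and 5 kb. Some of these 43 lie on scaffolds or patches and entered no comparison. With the others, gene ends stood at 2.97 times random (permutation p 0.0509) and the rest of protein-coding genes at 1.081. Other genes reversed to 1.303, and outside genes stood at 0.7312. Neighbour distance was 0.6217, and the share within 5 kb of another was 500 times a random share close to none. Several of these neighbours are the entries of high control level at and beside Rn18s-rs5. The longest genes stood at 1.184 and the shortest reversed to 0. By Fisher's exact test 0 lists then passed (1 at an unadjusted p under 0.05), and so few peaks leave few summits in any class. Lists past the threshold were 2 at q of 0.05 or less, where immediate early genes joined olfactory receptors, and 2 at 5 kb, where the protocadherin odds ratio reversed to 2.165 (adjusted p 0.0484, Fisher's exact test). Many protocadherin genes share an end, and a summit there counts for each, so that p is too small. The cause was not tested. The olfactory odds ratio was 0.24 to 0.53 in the settings that keep more peaks than these 43. The longest quintile fell to 1.007 against random positions within 50 kb and the shortest to 1.051 among genes with a summit, where requiring a summit fixes a minimum density in short genes. The difference in log2 fold at gene ends was 0 by medians and 0.02 by means (0.0152). Stratifying by promoter CpG, a background outside repeats, base composition and motifs were not run. Pileups near 15 fragments limit each single peak.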

Other observations

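The gene types in this part were compared only after the data were seen. MicroRNA and snoRNA genes had summits in or within 1 kb of the gene more often than random positions gave, while snRNA and tRNA genes did not. Of 1228 microRNA genes, 70 had one, 2.02 times random (1.43 to 3.18), with an adjusted permutation p of 0.0025 over 10 gene types, and 1.37 times (1.04 to 1.94) against positions within 50 kb, with an adjusted permutation p of 0.05. Of 1340 snoRNA genes, which guide the modification of ribosomal RNA, 57 had one, 1.44 times random (1.07 to 2.11; adjusted permutation p 0.024) and 1.62 times within 50 kb (1.16 to 2.48; adjusted permutation p 0.00999). Pseudogenes had 443 of 9852, 0.838 times random (0.779 to 0.906), but 1.00 times within 50 kb. Transcribed pseudogenes had 46 of 476, 0.784 times random and 1.12 times within 50 kb. Long noncoding RNA genes had 2739 of 12697, 1.07 times random (adjusted permutation p 0.0025) but 0.984 times within 50 kb (adjusted permutation p 0.357). Protein-coding genes had 8355 of 21631, 1.18 times random (adjusted permutation p 0.0025) and 1.05 times within 50 kb (adjusted permutation p 0.00999). Only 4 of 408 tRNA genes had one, 0.353 times random, with an adjusted permutation p of 0.0955, and 0.370 times within 50 kb (0.20 to 0.804; adjusted permutation p 0.144), and 21 of 1003 snRNA genes had one, 0.733 times random (0.552 to 1.11; adjusted permutation p 0.146) and 0.758 times within 50 kb. Pseudogenes of immunoglobulin and T cell receptor V segments had 9 of 153, 1.86 times random (adjusted permutation p 0.0812) but 3.36 times within 50 kb (adjusted permutation p 0.00999). The V segment genes themselves had 5 of 394, 0.419 times random (adjusted permutation p 0.0812) and 0.803 times within 50 kb (adjusted permutation p 0.754). Whether the host genes of microRNAs and snoRNAs account for their counts was not tested.

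Among peaks at the most common control level, which include 163 of the 190 on X, the density of X peaks relative to autosomes was 0.0938 at pileups up to 13, 0.112 at 14 to 15, 0.0925 at 16 to 17, 0.0567 at 18 to 19 and 0.0468 (0.00963 to 0.137) from 20, the last with 3 such X peaks.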
